A study of Agaricus bisporus with 12 samples.

How the data were processed

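Reads were mapped and counted by the authors, and the aligner and its settings are not given in the sources used here. As deposited, each library has its own table with the count of uniquely placed reads per gene, the gene's length and coverage, an RPKM, and KEGG, GO and nr annotation. Per the file headers the count values are unique reads per gene, made before deposition by mapping and counting, and they sum to the total each file states. The RPKM values as deposited equal count over gene length over that total, with no further scaling between libraries. A gene without a read in a library has no line in its table and was taken as 0, since the lowest count listed is 1.

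Gene numbers were matched to the locus tags of the H97 genome in RefSeq, which covered 9440 of 9502 genes (99.3%), and genes without a match are given by number alone. Strain A15 is not H97, so alleles that differ from the reference may have lost reads. No coordinates were used, the genome build the authors mapped to is not given in the sources used here, and strandedness is not stated, so values of overlapping genes are uncertain. Counting only unique reads leaves the levels of close paralogs, such as hydrophobins and laccases, uncertain. Descriptions were the nr name where it was informative (384 genes) and otherwise the KEGG orthology text (4213 genes), so 48.4% of genes had one. Of the latter, 361 rested on a weak match, which is why some names are given as annotations only. That reading of the list rule was set after the annotation was seen.

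Genes with enough reads in a stage (edgeR's filterByExpr, minimum count 10 and total 15) were tested, 8814 in all. Counts were scaled by TMM (factors 0.834 to 1.11) and fitted with edgeR's robust quasi-likelihood model over all 12 libraries with a term per stage, which left 6 residual degrees of freedom (common dispersion 0.022). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The SE of a log2 change is its size over the root of the F statistic. Gene lists were tested with camera (limma) on log2 CPM (prior 1) with a preset correlation of 0.01, adjusted over lists and comparisons together, two-sided, and again with a correlation estimated for each list. Lists added later were adjusted separately. With the preset correlation 71 pairs of list and comparison were called, and with the estimated one 0.

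The comparisons, lists, thresholds and rule for naming genes were fixed before the data were examined. The lists were laccases (12 genes, the laccase-2 small subunit among them), secreted heme peroxidases, the hydrogen peroxide list of sugar and alcohol oxidoreductases, cellulose, hemicellulose and pectin, chitin and wall glucan, starch with glycogen and trehalose, sugar transporters, pentose and polyol metabolism, glycolysis, proteases, nitrogen assimilation, cytochromes P450 with glutathione transferases, hydrophobins, fruiting body markers (tyrosinases, lectins, aegerolysins), ribosomal proteins, the respiratory chain, chaperones, autophagy, the proteasome and the cell cycle. Members were taken by their description, so a few sit there by name only: recyclin-1 (gene 136361) in the cell cycle list, a tRNA methyltransferase (gene 203362) in the respiratory list and glycogen synthase kinase 3 (gene 190701) in the starch list. Genes named for the largest rises and falls had an edgeR adjusted p under 0.05, libraries of the compared stages that did not overlap, a mean of at least 20 CPM in the higher stage and a description of function. List members needed only the adjusted p, so some are near the floor. For each step between consecutive stages the 5 largest rises and 5 largest falls were taken, for the other comparisons 3 of each, and from each list the called member with the largest rise and fall. Added to these were the 3 described genes with the lowest p for the difference between the after-flush steps. This gave 332 results in 169 genes. Each list's most abundant member and the 3 most abundant genes per stage are named besides and are not in that count.

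A self-test used simulated counts, drawn from the genes' mean levels, the library sizes and the trended dispersion, with no other stage effect. Changes were planted at first flush in 50 genes at each size. Against pinning, 18% were recovered at 1.5-fold, 76% at 2-fold, 98% at 4-fold and 100% at 8-fold. Few genes changed in the simulation and none had a spread of its own, so these shares need not hold for the real libraries. Of 155 calls in the simulation, 9 were false. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15.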

Results

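The libraries came from compost colonised by the mycelium of Agaricus bisporus strain A15, a commercial heterokaryon of the white button mushroom grown on straw and manure. Spawn was grown through the compost for 16 days at 25 °C, a casing of peat and lime was laid on top, and mushrooms were then picked in waves that growers call flushes. RNA was taken from the compost, not from picked mushrooms, at 6 stages with 2 libraries each. They were spawning, pinning (when mushroom primordia form), the first flush, the second flush, and a time after each flush. The series asks which plant-biomass-degrading functions the mycelium expresses at each of them.

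Reads placed uniquely in genes (in M, mega-reads) numbered 7.27 and 7.43 in the spawning libraries, 9.02 and 8.48 at pinning and 8.99 and 9.11 at first flush. They numbered 8.41 and 8.79 after first flush, 9.11 and 9.34 at second flush and 9.18 and 9.22 after second flush. Between 9189 and 9270 genes had a read in each library, and 8814 genes were tested. Levels are in RPKM (reads scaled to gene length and library total), given as mean ± SD over the 2 libraries of a stage. Genes are named by the description in the files and by the gene number, which in 99.3% of cases is the locus tag number of the H97 strain's genome. Nothing in the labels says whether the 2 libraries of a stage came from separate beds, so p-values measure only the spread between these samples, which may be technical. The first flush libraries carry another letter in the submitters' library codes than the other 10, so a library batch, if there was one, and the first flush cannot be told apart.

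Across genes, the libraries of a stage correlated at 0.982 to 0.996 in log2 CPM, against 0.886 to 0.981 between stages (Pearson; genes are not independent replicates). The pair from after first flush was the least alike, with 341 genes over 2-fold apart, against 23 at pinning, 26 at spawning, 102 at first flush, 172 at second flush and 105 after second flush. Over the 6 stages, 7547 genes (85.6%) changed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05.

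An uncharacterised gene (gene 136557) had the highest level of any gene at spawning (21083 ± 117 RPKM), pinning (34950 ± 1184), first flush (25875 ± 2602), after first flush (8918 ± 1435) and second flush (11803 ± 3372). It was followed at each of those stages by a pair of hydrophobins, small secreted proteins that coat fungal surfaces (genes 136569 and 193057), at 13895 ± 541 and 18727 ± 1129 RPKM in spawning compost. Close to these at spawning were the laccase-2 small subunit (gene 149407, 13140 ± 275 RPKM) and laccase-2 (gene 139148, 10478 ± 366 RPKM). After second flush the order was different: elongation factor 1-alpha (gene 133083, 6502 ± 381 RPKM) and ubiquitin (gene 133168, 5050 ± 713 RPKM) came first, and hydrophobin 136569 had 3169 ± 350 RPKM.

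**Figure D1:**
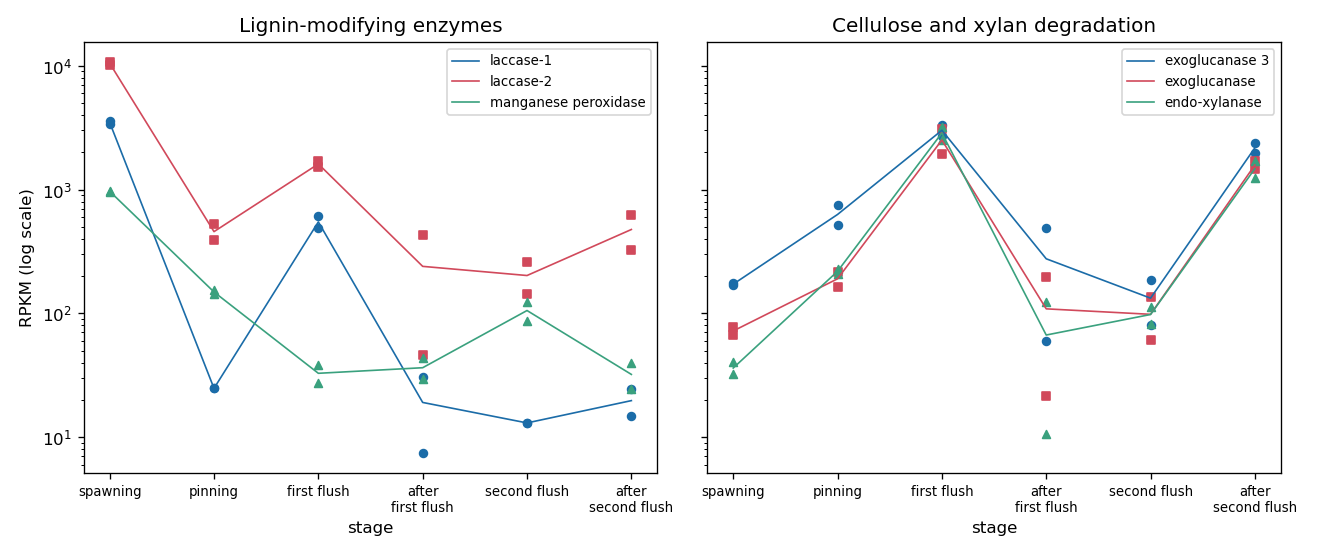
RPKM on a log axis of laccase-1, laccase-2 and manganese peroxidase (left) and of exoglucanase 3, another exoglucanase and an endo-xylanase (right) by stage, with points for single libraries and lines through stage means. Laccase-1 stood at 3485 RPKM at spawning, 24.7 at pinning and 548 at first flush, whereas exoglucanase 3 stood at 172, 629 and 3012.

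Between spawning and pinning laccase-1 and manganese peroxidase, enzymes that oxidise lignin, fell. Laccase-1 (lcc1, gene 146228), a secreted phenol oxidase, went from 3485 ± 165 to 24.7 ± 0.011 RPKM (log2 change −7.27, SE 0.65, edgeR adjusted p = 4.7e-05). Manganese peroxidase (gene 221245), the one secreted heme peroxidase among the described genes, went from 968 ± 11 to 149 ± 6.7 RPKM (−2.84, SE 0.29, edgeR adjusted p = 2.5e-05). A gene annotated as 2,3-dihydroxybenzoate decarboxylase (gene 210050), an enzyme class that acts on aromatic acids, fell from 112 ± 7.5 to 0.924 ± 0.079 RPKM (−7.02, SE 0.29, edgeR adjusted p = 6.2e-08). A cutinase (gene 190200), which splits the plant polyester cutin, fell from 175 ± 31 to 2.63 ± 0.33 RPKM (−6.18, SE 0.23, edgeR adjusted p = 3.7e-08). A saccharopepsin-like aspartic protease (gene 212363) fell from 176 ± 1.2 to 2.59 ± 0.39 RPKM (−6.21, SE 0.43, edgeR adjusted p = 4.5e-06).

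Of the 12 genes of the laccase list, which counts the laccase-2 small subunit as 1, 7 fell, 1 rose and 4 were not called (camera adjusted p = 0.045, adjusted p = 0.46 with an estimated correlation; 0.055 with DESeq2 size factors, which ends the call). The riser was laccase-7 (gene 117501), at 8.37 ± 0.82 and then 39 ± 7.7 RPKM. Together the laccases held 3.06% of all reads at spawning and 0.153% at pinning. In the list of cytochromes P450 and glutathione transferases, which handle aromatic and foreign compounds, 38 of 74 genes fell and 11 rose (camera adjusted p = 0.00011, adjusted p = 0.31 with an estimated correlation); glutathione transferase 193900 went from 442 ± 14 to 41.2 ± 4 RPKM. The hydrogen peroxide list, made of sugar and alcohol oxidases and dehydrogenases, had 20 of 43 genes lower and 7 higher (camera adjusted p = 0.0081, adjusted p = 0.48 with an estimated correlation), with pyranose dehydrogenase (gene 230189) among the risers (17.7 ± 6.3 to 207 ± 16 RPKM, not called without spawning replicate 2). Chitin and fungal wall genes had 16 of 28 lower and 2 higher (camera adjusted p = 0.00078, adjusted p = 0.48 with an estimated correlation). Starch, glycogen and trehalose genes had 14 of 20 lower and none higher (camera adjusted p = 0.00025, adjusted p = 0.48 with an estimated correlation), alpha-amylase 211295 falling from 18.6 ± 1.1 to 0.844 ± 0.093 RPKM.

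Of 93 ribosomal protein genes, 77 rose and 3 fell (camera adjusted p = 1.7e-17, adjusted p = 0.5 with an estimated correlation), and their share of reads went from 1.84% to 4.57%. Of 62 respiratory chain genes 45 rose and 5 fell (camera adjusted p = 1.4e-06, adjusted p = 0.51 with an estimated correlation). Glycolysis had 11 of 18 genes higher and 2 lower (camera adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation), enolase 189297 going from 99.4 ± 7.7 to 439 ± 39 RPKM. Proteasome genes had 27 up and 6 down of 48 (camera adjusted p = 0.0034, adjusted p = 0.74 with an estimated correlation). Cell cycle genes had 16 up and 4 down of 47 (camera adjusted p = 0.015, adjusted p = 0.46 with an estimated correlation). Autophagy genes had 6 of 9 up and none down (camera adjusted p = 0.02, adjusted p = 0.48 with an estimated correlation).

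Neither list for plant wall sugars was called at pinning. Cellulose genes had 11 up and 12 down of 39 (camera adjusted p = 1). Hemicellulose and pectin genes had 9 up and 8 down of 32 (camera adjusted p = 0.98). Among fruiting body markers an XCL-like lectin (gene 75698) rose from 4.14 ± 1.9 to 170 ± 47 RPKM (5.22, SE 1.02, edgeR adjusted p = 0.0037), while the list had 3 of 11 up and 3 down (camera adjusted p = 0.99). Other lists were not called either. Hydrophobins had 2 up and 1 down of 5 (camera adjusted p = 0.63). Proteases had 6 up and 14 down of 40 (camera adjusted p = 0.11). Chaperones had 9 up and 15 down of 41 (camera adjusted p = 0.29). Pentose and polyol genes had 5 up and 2 down of 10 (camera adjusted p = 0.34, median 0.73 but mean −0.14). Nitrogen genes had 14 up and 13 down of 37 (camera adjusted p = 0.99, median 0.11 but mean −0.07). Of the UDP-sugar transporters, a list too short to test, 1 fell and 1 was not called. Adjusted over the list alone, the counts up and down were 1 and 8 for laccases, 11 and 39 for P450 and glutathione transferase genes, 7 and 21 for the hydrogen peroxide list, 2 and 18 for wall genes, 10 and 8 for hemicellulose and pectin, 28 and 7 for the proteasome, 15 and 4 for the cell cycle, 5 and 13 for proteases, 10 and 17 for chaperones and 14 and 14 for nitrogen genes, and as above for the other lists.

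In all, 2579 genes rose and 2220 fell at pinning in edgeR's test. In limma on log2 of the deposited RPKM (pseudocount 1, 9006 genes), without further scaling, 3030 rose and 1812 fell (62.6% up, against 53.7%). The median change of all genes moved by 0.13 on the log2 scale. The test and the genes differ from edgeR's as well as the scaling, here and wherever unscaled RPKM is given below.

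From pinning to first flush the cellulose list and the hemicellulose and pectin list were called as higher, though members of each fell too. With an estimated correlation camera called neither. Exoglucanase 3 (gene 190390), a cellobiohydrolase and the most abundant member of the cellulose list, stood at 629 ± 162 and then 3012 ± 444 RPKM, a difference that did not pass on its own (edgeR adjusted p = 0.086). The cellulose-growth-specific protein 226235 rose from 3.1 ± 0.47 to 383 ± 95 RPKM (log2 change 6.71, SE 1.10, edgeR adjusted p = 0.0022), and endo-xylanase 194858 from 4.32 ± 1.1 to 193 ± 14 RPKM (5.25, SE 0.74, edgeR adjusted p = 0.00088). Chitinase 188164 (0.427 ± 0.065 to 84.3 ± 64 RPKM; 7.37, SE 0.72, edgeR adjusted p = 0.0001) and a gene annotated as endo-1,3(4)-beta-glucanase (gene 195916; 0.384 ± 0.061 to 156 ± 75 RPKM; 8.38, SE 0.50, edgeR adjusted p = 1.8e-06), enzymes of chitin and beta-glucan, were among the largest rises of described genes. Laccase-1 rose to 548 ± 87 RPKM (4.24, SE 0.57, edgeR adjusted p = 0.00057), whereas manganese peroxidase fell again, to 32.7 ± 7.8 RPKM (−2.40, SE 0.29, edgeR adjusted p = 0.00012).

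By list, 21 of 39 cellulose genes rose and 9 fell (camera adjusted p = 0.022, adjusted p = 0.56 with an estimated correlation). That list took in 16 glucan 1,3-beta-glucosidases, which act on fungal-type glucan. Without them 16 of 23 genes rose and 4 fell (camera adjusted p = 0.0031, adjusted p = 0.4 with an estimated correlation), a subset chosen after the data were seen. Of these 23 genes, 4 also sit in the hemicellulose and pectin list, so the lists are not independent. Hemicellulose and pectin genes had 16 of 32 up and 4 down (camera adjusted p = 0.043, adjusted p = 0.75 with an estimated correlation). Endo-xylanase 79647 led them (13.4 ± 4.7 to 685 ± 132 RPKM), although its call was lost without either pinning library. The list's largest fall was in a polygalacturonase (gene 229720), which splits pectin, from 4.64 ± 0.34 to 0.619 ± 0.061 RPKM, a call lost without any 1 of the 4 libraries. Laccases had 5 of 12 up, none down (camera adjusted p = 0.0039, adjusted p = 0.31 with an estimated correlation). Wall genes had 12 of 28 up and 2 down (camera adjusted p = 0.038, adjusted p = 0.56 with an estimated correlation). The respiratory chain moved the other way, with 51 of 62 genes lower and none higher (camera adjusted p = 3.8e-14, adjusted p = 0.37 with an estimated correlation). With p-values adjusted over the list alone, the counts up and down were 18 and 4 for cellulose genes without the glucan 1,3-beta-glucosidases and as above for the others. The XCL-like lectin 194894 fell from 1419 ± 359 to 70.2 ± 8.3 RPKM (−4.56, SE 0.78, edgeR adjusted p = 0.0024). A gene annotated as trichodiene synthase, a terpene cyclase (gene 209957), fell from 306 ± 203 to 2.13 ± 0.29 RPKM (−7.38, SE 1.26, edgeR adjusted p = 0.0027).

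The first flush call counts were 2215 up and 2081 down, so that 51.6% of called genes rose. On unscaled RPKM that share was 68.3%, with the median of all genes shifted by 0.22, and every statement about first flush holds for libraries that share a code letter.

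**Figure D2:**
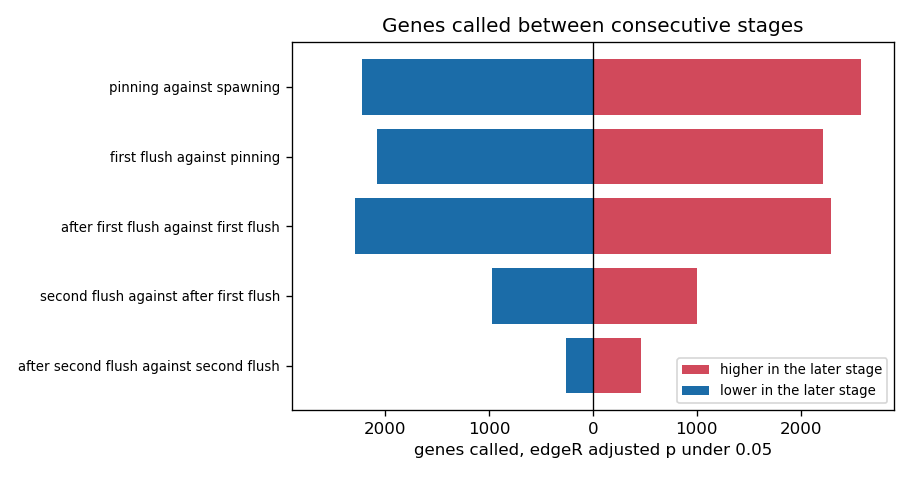
Genes higher (right) and lower (left) in the later of 2 consecutive stages, as bars from 0 on an axis of gene counts (edgeR adjusted p under 0.05). The bars are longest for pinning against spawning (2579 higher, 2220 lower) and shortest for after second flush against second flush (466 higher, 255 lower).

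After first flush the laccases, the cellulose list and the hemicellulose and pectin list were called as lower, though none of them with an estimated correlation in camera. Endo-xylanase 196181 went from 2862 ± 500 to 66.7 ± 79 RPKM (log2 change −5.44, SE 0.99, edgeR adjusted p = 0.0032, but 0.068 when only these stages' libraries were fitted), endoglucanase 194478 from 425 ± 31 to 10.9 ± 9.9 RPKM (−5.30, SE 0.66, edgeR adjusted p = 0.00041) and laccase-1 from 548 ± 87 to 19 ± 16 RPKM (−4.87, SE 0.59, edgeR adjusted p = 0.00028). The opposite change was seen in pyruvate decarboxylase (gene 193820), the entry step of ethanol fermentation, at 44.5 ± 1.1 and then 1054 ± 496 RPKM (4.54, SE 0.28, edgeR adjusted p = 1.2e-06), and in the mitochondrial alternative oxidase (gene 152135), which passes electrons to oxygen around the cytochrome pathway, at 26.2 ± 1.5 and then 515 ± 451 RPKM (4.27, SE 0.68, edgeR adjusted p = 0.0015). A gene annotated as a multidrug transporter of the DHA1 family (gene 145318) rose from 0.39 ± 0.25 to 28.1 ± 2.5 RPKM (6.11, SE 0.34, edgeR adjusted p = 4.8e-07). The libraries of this stage stood far apart in some genes: AGABI2DRAFT_190390, exoglucanase 3, stood at 60.2 RPKM in replicate 1 and 491 in replicate 2, and AGABI2DRAFT_152135, the alternative oxidase, at 834 and 197.

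Of the hemicellulose and pectin list 24 of 32 genes fell and 2 rose (camera adjusted p = 4.7e-07, adjusted p = 0.51 with an estimated correlation). The riser with the largest change was an arabinan endo-arabinosidase (gene 119499; 4.05 ± 1.2 to 59 ± 41 RPKM). Of the cellulose list 24 of 39 fell and 7 rose (camera adjusted p = 0.00019, adjusted p = 0.48 with an estimated correlation), endoglucanase 196143 being a riser (90.6 ± 6.2 to 347 ± 67 RPKM). Laccases had 8 of 12 down and none up (camera adjusted p = 0.00078, adjusted p = 0.31 with an estimated correlation). Wall genes had 14 of 28 down and 3 up (camera adjusted p = 0.012, adjusted p = 0.51 with an estimated correlation). Proteasome genes had 28 of 48 down and 7 up (camera adjusted p = 0.0034, adjusted p = 0.74 with an estimated correlation). Respiratory chain genes rose, 53 of 62 against 2 down (camera adjusted p = 3e-15, adjusted p = 0.36 with an estimated correlation), as did ribosomal protein genes, 33 of 93 against 5 down (camera adjusted p = 0.0019, adjusted p = 0.75 with an estimated correlation). In lists drawn up after the data were seen, 17 of 23 cellulose genes other than glucan 1,3-beta-glucosidases fell and 5 rose (camera adjusted p = 0.0002, adjusted p = 0.32 with an estimated correlation). In the other lists of this kind, 12 of 25 sugar porters of the SP family fell and 4 rose (camera adjusted p = 0.043, adjusted p = 0.21 with an estimated correlation), and 8 of 17 glucan 1,3-beta-glucosidases fell and 2 rose (camera adjusted p = 0.043, adjusted p = 0.25 with an estimated correlation). Counted as adjusted over the list alone, the counts up and down were 2 and 25 for hemicellulose and pectin, 7 and 26 for cellulose, 7 and 30 for the proteasome, 4 and 13 for SP-family porters, 2 and 9 for glucan 1,3-beta-glucosidases, 5 and 17 for the other cellulose genes, 54 and 2 for the respiratory chain and 31 and 4 for ribosomal proteins, and as above for laccases and wall genes. The replicates of this stage differed within these groups too: hemicellulose and pectin genes took 0.0707% and 0.163% of reads, laccases 0.0514% and 0.127%, and fruiting body markers 0.11% and 0.0429%.

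In all, 2297 genes rose and 2294 fell after first flush. This step is measured against the first flush libraries, so their code letter applies to it too. The same libraries serve in the step before, so a rise to first flush and a fall after it are not independent.

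From after first flush to second flush the enzyme lists for lignin, cellulose and hemicellulose were not called: 1 laccase of 12 rose (camera adjusted p = 0.55), 5 of 39 cellulose genes rose and 1 fell (camera adjusted p = 0.2), and 3 of 32 hemicellulose and pectin genes rose and 3 fell (camera adjusted p = 0.52, median −0.06 with a test direction of up). Manganese peroxidase rose from 36.3 ± 10 to 105 ± 27 RPKM (log2 change 1.67, SE 0.28, edgeR adjusted p = 0.0042). Glutamine synthetase (gene 190498), which fixes ammonium, rose from 13.7 ± 6.4 to 95.6 ± 32 RPKM (2.92, SE 0.45, edgeR adjusted p = 0.0043). An aquaporin-type water channel (gene 195899) rose from 10 ± 1.7 to 69.6 ± 28 RPKM (2.91, SE 0.36, edgeR adjusted p = 0.0016). Pyruvate decarboxylase fell from 1054 ± 496 to 137 ± 14 RPKM (−2.82, SE 0.26, edgeR adjusted p = 0.00034). Hydrophobin-1 (AGABI2DRAFT_133693) had the largest rise among the genes named for this step (6.58, SE 1.63, edgeR adjusted p = 0.03), and its size rested on 1 library: replicate 1 of second flush stood at 421.7 RPKM and replicate 2 at 10.8, and the change was 2.33 without replicate 1. Its call was lost without either library of after first flush.

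Ribosomal protein genes had 33 of 93 lower and 1 higher (camera adjusted p = 1.3e-09, adjusted p = 0.56 with an estimated correlation). Respiratory chain genes had 18 of 62 lower and 1 higher (camera adjusted p = 2.1e-05, adjusted p = 0.52 with an estimated correlation). Cell cycle genes had 13 of 47 lower and 1 higher (camera adjusted p = 0.0013, adjusted p = 0.35 with an estimated correlation). Starch, glycogen and trehalose genes had 5 of 20 higher and none lower (camera adjusted p = 0.00087, adjusted p = 0.51 with an estimated correlation). Chaperones had 12 of 41 higher and 2 lower (camera adjusted p = 0.023, adjusted p = 0.48 with an estimated correlation), with heat shock protein 70 (gene 133986) at 1608 ± 104 and then 3622 ± 415 RPKM. The proteasome list was called upward (camera adjusted p = 0.012, adjusted p = 0.75 with an estimated correlation) on 2 genes up, 2 down and 44 not called. Adjusted over the list alone, the counts up and down were 2 and 45 for ribosomal proteins, 1 and 19 for the respiratory chain, 1 and 17 for the cell cycle, 6 and 0 for starch, 14 and 3 for chaperones, 0 and 0 for the proteasome, 3 and 2 for hemicellulose and pectin, and as above for laccases and cellulose.

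Here 1000 genes rose and 967 fell, and the count of 1967 fell to 1226 without second flush replicate 1 and to 809 without replicate 2. Fitted on these 4 libraries alone, 46 genes were called, and 34 of the 38 genes named for this comparison lost their call, the aquaporin and pyruvate decarboxylase not among them; on unscaled RPKM 30.9% of called genes rose, against 50.8%, and the median of all genes moved by −0.12.

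After second flush the hemicellulose and pectin list and the cellulose list were called as higher, and the laccases were not. No list call here held when camera used an estimated correlation. Endo-xylanase 136707 went from 12.2 ± 2.3 to 346 ± 12 RPKM (log2 change 4.78, SE 0.30, edgeR adjusted p = 2.6e-05), endo-xylanase 194858 from 6.59 ± 2.8 to 195 ± 14 RPKM (4.84, SE 0.70, edgeR adjusted p = 0.008, lost without second flush replicate 2) and the cellulose-growth-specific protein 226235 from 7.46 ± 4.2 to 321 ± 58 RPKM (5.38, SE 0.99, edgeR adjusted p = 0.022, lost without any 1 of the 4 libraries). Exoglucanase 3 stood at 133 ± 74 and then 2175 ± 293 RPKM. Among the falls were glutamine synthetase, back to 15.1 ± 7.9 RPKM (−2.69, SE 0.44, edgeR adjusted p = 0.0094), a tyrosinase (gene 135027; 86 ± 31 to 16.5 ± 4 RPKM; −2.43, SE 0.31, edgeR adjusted p = 0.0025), which oxidises phenols to melanin precursors, and the abundant hydrophobin 193057 (10073 ± 3835 to 2419 ± 663 RPKM; −2.11, SE 0.31, edgeR adjusted p = 0.0039). Manganese peroxidase fell to 32.1 ± 11 RPKM (−1.78, SE 0.28, edgeR adjusted p = 0.0052).

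Of the hemicellulose and pectin genes 22 of 32 rose and none fell (camera adjusted p = 1.1e-20, adjusted p = 0.31 with an estimated correlation). Of the cellulose genes 17 of 39 rose and 2 fell (camera adjusted p = 8.2e-07, adjusted p = 0.36 with an estimated correlation). None of the 12 genes of the laccase list was called by edgeR (camera adjusted p = 0.46). Pentose and polyol genes had 5 of 10 up (camera adjusted p = 0.013, adjusted p = 0.51 with an estimated correlation). Glycolysis had 5 of 18 up and 1 down (camera adjusted p = 0.0025, adjusted p = 0.51 with an estimated correlation). Proteases had 4 of 40 up (camera adjusted p = 0.031, adjusted p = 0.68 with an estimated correlation). The cell cycle list had 8 of 47 up and 1 down (camera adjusted p = 0.013, adjusted p = 0.46 with an estimated correlation). Hydrophobins had 3 of 5 down (camera adjusted p = 3.5e-05, adjusted p = 0.31 with an estimated correlation). Fruiting body markers had 1 of 11 down (camera adjusted p = 0.0055, adjusted p = 0.51 with an estimated correlation). The respiratory chain had 2 of 62 down (camera adjusted p = 4e-05, adjusted p = 0.52 with an estimated correlation). With p-values adjusted over the list alone, the counts up and down were 26 and 0 for hemicellulose and pectin, 19 and 3 for cellulose, 0 and 0 for laccases, 5 and 1 for pentose genes, 7 and 2 for glycolysis, 4 and 0 for proteases, 11 and 2 for the cell cycle, 0 and 4 for hydrophobins, 0 and 2 for fruiting body markers and 0 and 0 for the respiratory chain.

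In the fit of all 12 libraries this step had the fewest calls, 466 up and 255 down. With only the stages compared in the fit, the step before it had fewer (46 calls). The count of 721 fell to 330 and 304 without second flush replicates 1 and 2, to 177 without after second flush replicate 1, and to 426 when only these 4 libraries were fitted. In fits chosen after the data were seen, it was 577 with the first flush libraries kept out of the spread and 1194 with the after first flush libraries kept out.

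**Figure D3:**
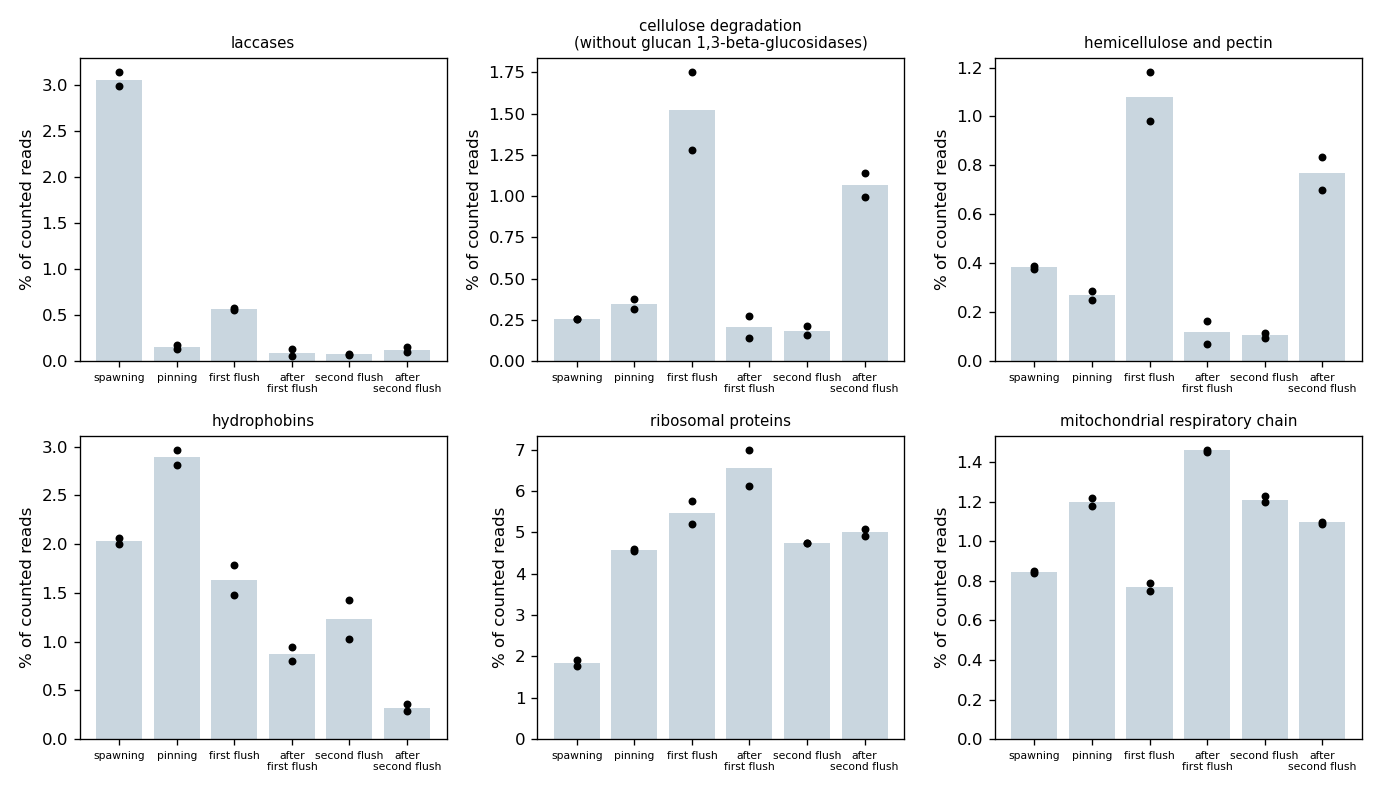
Percentage of each library's counted reads in 6 gene lists (one panel each) by stage, with bars for the mean of the 2 libraries and points for single libraries. Hemicellulose and pectin genes held 1.08% at first flush, 0.105% at second flush and 0.767% after second flush, while laccases held 3.06% at spawning and 0.561% at first flush.

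The flushes were then set against each other. At second flush laccase-1 was lower than at first flush (13 ± 0.12 against 548 ± 87 RPKM; log2 change −5.29, SE 0.60, edgeR adjusted p = 0.00024), as were chitinase 188164 (1.43 ± 0.025 against 84.3 ± 64 RPKM; −5.76, SE 0.61, edgeR adjusted p = 0.00014) and a xylanase with an acetylxylan esterase annotation (gene 192194; 2.45 ± 0.23 against 125 ± 15 RPKM; −5.56, SE 0.58, edgeR adjusted p = 0.00011). Manganese peroxidase was higher (105 ± 27 against 32.7 ± 7.8 RPKM; 1.79, SE 0.28, edgeR adjusted p = 0.00059). Hemicellulose and pectin genes had 21 of 32 lower and 1 higher (camera adjusted p = 6.6e-07, adjusted p = 0.51 with an estimated correlation). Cellulose genes had 20 of 39 lower and 7 higher (camera adjusted p = 0.0019, adjusted p = 0.51 with an estimated correlation). Laccases had 8 of 12 lower (camera adjusted p = 9.8e-05, adjusted p = 0.31 with an estimated correlation). Wall genes had 11 of 28 lower and 5 higher (camera adjusted p = 0.045, adjusted p = 0.56 with an estimated correlation). Cell cycle genes had 24 of 47 lower and 6 higher (camera adjusted p = 0.0019, adjusted p = 0.35 with an estimated correlation). Respiratory chain genes had 43 of 62 higher and none lower (camera adjusted p = 2.4e-10, adjusted p = 0.46 with an estimated correlation). Counted as adjusted over the list alone, the counts up and down were 0 and 10 for laccases, 7 and 27 for the cell cycle and 46 and 1 for the respiratory chain, and as above for the other lists named here. In all, 2025 genes were higher and 2003 lower at second flush, but on unscaled RPKM 1659 were higher and 2262 lower (42.3% up, against 50.3%). With at least a 2-fold change 783 were higher and 1017 lower, and the code letter of the first flush libraries applies to each of these differences. A swap of the second flush and after second flush labels, weighed below, was not excluded, and it bears on every comparison with those stages. With it, the second flush share of hemicellulose and pectin genes would be 0.767% of reads, not 0.105%, against 1.08% at first flush.

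Against spawning, the mean of the 5 later stages was lower in several genes that had fallen at pinning. Laccase-1 was lower by a log2 change of −6.86 (SE 0.32, edgeR adjusted p = 6.7e-07), manganese peroxidase by −4.37 (SE 0.17, edgeR adjusted p = 2.6e-08), the saccharopepsin-like protease 212363 by −8.35 (SE 0.26, edgeR adjusted p = 1.6e-08) and glutathione transferase 193900 by −5.06 (SE 0.16, edgeR adjusted p = 6.9e-09). A gene with a weak match to clathrin heavy chain (gene 180174) fell from 811 ± 14 RPKM at spawning to between 0.444 ± 0.014 and 5.19 ± 0.95 RPKM at the later stages (−9.40, SE 0.11, edgeR adjusted p = 1.4e-13). Tyrosinase 191507 (3.36, SE 0.44, edgeR adjusted p = 0.00019) and carboxypeptidase 187563 (2.52, SE 0.24, edgeR adjusted p = 3.1e-06) were higher. The laccases, with 7 of 12 lower and 3 higher, did not pass as a list (camera adjusted p = 0.074). P450 and glutathione transferase genes had 43 lower and 12 higher of 74 (camera adjusted p = 0.00015, adjusted p = 0.31 with an estimated correlation). The hydrogen peroxide list had 25 lower and 9 higher of 43 (camera adjusted p = 0.011, adjusted p = 0.48 with an estimated correlation). Starch genes had 15 lower and 2 higher of 20 (camera adjusted p = 0.00078, adjusted p = 0.51 with an estimated correlation). Wall genes had 15 lower and 4 higher of 28 (camera adjusted p = 0.011, adjusted p = 0.51 with an estimated correlation).

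Other lists were called as higher than at spawning. Ribosomal proteins had 78 higher and 7 lower of 93 (camera adjusted p = 1.3e-15, adjusted p = 0.51 with an estimated correlation). The respiratory chain had 43 higher and 8 lower of 62 (camera adjusted p = 0.00067, adjusted p = 0.56 with an estimated correlation). The proteasome had 29 higher and 5 lower of 48 (camera adjusted p = 0.002, adjusted p = 0.72 with an estimated correlation). Glycolysis had 13 higher and 3 lower of 18 (camera adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation). The cell cycle had 27 higher and 5 lower of 47 (camera adjusted p = 0.016, adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, the counts up and down were 3 and 8 for laccases, 12 and 44 for P450 and glutathione transferase genes, 79 and 7 for ribosomal proteins and 43 and 10 for the respiratory chain, and as above for the other lists. In all, 3032 genes were higher and 2783 lower, so that 52.1% of called genes were higher; on unscaled RPKM that share was 69.8%, with the median of all genes shifted by 0.28.

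The last comparison averaged the step from a flush to the stage after it over both flushes. Pyruvate decarboxylase was higher after a flush on average (log2 change 2.68, SE 0.18, edgeR adjusted p = 1.2e-05), as was the alternative oxidase (2.55, SE 0.45, edgeR adjusted p = 0.0044). For both genes the step after first flush was larger than this average, and the step after second flush smaller. Tyrosinase 135027 (−2.65, SE 0.22, edgeR adjusted p = 6.3e-05), laccase-5 (gene 135711; −2.46, SE 0.29, edgeR adjusted p = 0.00038) and hydrophobin 193052 (−1.71, SE 0.21, edgeR adjusted p = 0.00033) were lower. Respiratory chain genes had 42 of 62 up and 2 down (camera adjusted p = 8.3e-11, adjusted p = 0.46 with an estimated correlation). Ribosomal proteins had 19 of 93 up and 1 down (camera adjusted p = 0.0039, adjusted p = 0.75 with an estimated correlation). Laccases had 6 of 12 down (camera adjusted p = 0.0022, adjusted p = 0.31 with an estimated correlation). Hydrophobins had 3 of 5 down (camera adjusted p = 0.0039, adjusted p = 0.31 with an estimated correlation). Fruiting body markers had 5 of 11 down (camera adjusted p = 0.02, adjusted p = 0.56 with an estimated correlation). Wall genes had 11 of 28 down and 3 up (camera adjusted p = 0.016, adjusted p = 0.52 with an estimated correlation). Starch genes had 6 of 20 down and 1 up (camera adjusted p = 0.018, adjusted p = 0.56 with an estimated correlation). Chaperones had 19 of 41 down and 8 up (camera adjusted p = 0.045, adjusted p = 0.51 with an estimated correlation). The proteasome had 16 of 48 down and 5 up (camera adjusted p = 0.0068, adjusted p = 0.75 with an estimated correlation). With p-values adjusted over the list alone, the counts up and down were 45 and 2 for the respiratory chain, 11 and 1 for ribosomal proteins, 0 and 6 for fruiting body markers, 4 and 11 for wall genes, 9 and 22 for chaperones and 5 and 17 for the proteasome, and as above for the rest. Not every average held for both flushes. After second flush alone the respiratory chain was called lower (median −0.2, camera adjusted p = 4e-05, adjusted p = 0.52 with an estimated correlation). In that step no laccase and no proteasome gene was called, and ribosomal proteins had 0 up and 1 down. Wall genes had 3 up and 1 down there (camera adjusted p = 0.72) and starch genes 1 up and 2 down (camera adjusted p = 0.32). Chaperones had 1 up and 1 down (camera adjusted p = 0.16). Hydrophobins and fruiting body markers were called lower in that step, as given above.

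This average covers steps that were not alike. The step differed between the flushes in 3471 genes, 1706 in favour of the second and 1765 of the first (edgeR test of the difference). The first flush libraries enter both the average and the difference, so a library batch, if there was one, cannot be told apart from either. The hemicellulose and pectin list differed, with 26 of 32 genes having the higher step after second flush and 1 the lower (camera adjusted p = 4.5e-13, adjusted p = 0.42 with an estimated correlation), and the respiratory chain differed the other way in 52 of 62 genes (camera adjusted p = 6.4e-17, adjusted p = 0.35 with an estimated correlation). The step was higher after second flush for 22 of 39 cellulose genes and lower for 5 (camera adjusted p = 2.2e-06, adjusted p = 0.37 with an estimated correlation). It was higher for 8 of 12 laccases (camera adjusted p = 0.00076, adjusted p = 0.31 with an estimated correlation). Wall genes had 11 of 28 higher and 4 lower (camera adjusted p = 0.016, adjusted p = 0.52 with an estimated correlation). Proteases had 16 of 40 higher and 4 lower (camera adjusted p = 0.013, adjusted p = 0.6 with an estimated correlation). The proteasome had 18 of 48 higher and 2 lower (camera adjusted p = 0.0061, adjusted p = 0.75 with an estimated correlation). The cell cycle list had 16 of 47 higher and 6 lower (camera adjusted p = 0.031, adjusted p = 0.48 with an estimated correlation). Ribosomal proteins had 17 of 93 lower and 2 higher (camera adjusted p = 0.014, adjusted p = 0.79 with an estimated correlation). For this difference the counts higher and lower, adjusted over the list alone, were 26 and 1 for hemicellulose and pectin, 1 and 53 for the respiratory chain, 22 and 5 for cellulose, 9 and 0 for laccases, 11 and 5 for wall genes, 19 and 4 for proteases, 18 and 2 for the proteasome, 16 and 6 for the cell cycle and 1 and 10 for ribosomal proteins. In all, 1663 genes were higher and 1526 lower after a flush on average. These counts take the spread within stages: when the 8 libraries were fitted as 4 against 4, so that the difference between flushes counted as spread, 1 gene was called.

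The lists drawn up after the data were seen were tested in every comparison. Sugar porters of the SP family, which carry sugars across membranes, had 9 of 25 up and 1 down at first flush (camera adjusted p = 0.11) and 7 up and 13 down at pinning (camera adjusted p = 0.13). At second flush 2 rose and 3 fell (camera adjusted p = 0.8, median 0.02 with a test direction of down). After second flush 6 rose and 1 fell (camera adjusted p = 0.027, adjusted p = 0.18 with an estimated correlation). Between the flushes 11 were lower and 3 higher at the second (camera adjusted p = 0.024, adjusted p = 0.18 with an estimated correlation). For the difference between the after-flush steps 10 were higher and 4 lower (camera adjusted p = 0.02, adjusted p = 0.18 with an estimated correlation). The cellulose genes other than glucan 1,3-beta-glucosidases had 16 of 23 up and none down after second flush (camera adjusted p = 1.3e-14, adjusted p = 0.18 with an estimated correlation). They had 16 lower and 4 higher at second than at first flush (camera adjusted p = 0.00017, adjusted p = 0.32 with an estimated correlation). In the difference between the after-flush steps 17 were higher and 2 lower (camera adjusted p = 4.9e-08, adjusted p = 0.25 with an estimated correlation). Of 17 glucan 1,3-beta-glucosidases 6 were lower and none higher after a flush (camera adjusted p = 0.043, adjusted p = 0.25 with an estimated correlation). These counts, adjusted over the list alone, were 17 and 0 for cellulose genes after second flush, 4 and 17 for them between the flushes and 11 and 4 for porters in the difference, and as above for the rest.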

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

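The tests of a library batch, a label swap, the mixtures and the other splits were chosen only after the result was seen. The step from a flush to the stage after it differed between the flushes in 3471 genes (edgeR's test of the difference, adjusted p under 0.05), which is what singled out each value here. Positive values mean a higher step after second flush. The first flush libraries enter this difference, so a batch behind their code letter, if there was one, cannot be told apart from it.

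A gene annotated as pappalysin-1, a metalloprotease (gene 134948), differed by 7.54, falling after first flush by a log2 change of −4.17 and rising after second flush by 3.37. A gene annotated as a sugar porter of the SP family and as a sterol glucosyltransferase (gene 195861) differed by 4.23, and an arabinogalactan endo-beta-galactosidase (gene 225045), an enzyme of plant pectin side chains, by 3.63. These are the described genes with the lowest p for the difference. Among lists called by camera, the median difference was 4.38 for hemicellulose and pectin, 1.95 for laccases, 0.83 for cellulose, 0.65 for chitin and wall glucan, 0.45 for the proteasome, 0.44 for proteases and 0.39 for the cell cycle. It was −0.22 for ribosomal proteins and −1.16 for the respiratory chain. The cellulose list took in 16 glucan 1,3-beta-glucosidases. In lists drawn up later, the median was 6.12 for its other 23 genes and 0.59 for 17 such glucosidases (not called by camera). With an estimated correlation 0 of these list calls remain.

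The first pattern is the set of cellulose, hemicellulose and pectin genes that rose at first flush. Genes matched in length to the members that rose had a median change of 0.03 (quartiles −0.46 and 0.53, 1472 genes), so genes of those lengths did not rise as a group. The members' own median of 2.08 is high by selection, since only called risers were taken. The median of all genes after scaling was as low (0.034), so the comparison does not decide on gene length. Over the whole lists the median change was 1.03 for cellulose and 0.85 for hemicellulose and pectin. A library batch shared by the first flush libraries cannot be told apart from the stage, since no first flush library carries the other code letter. The 33 members that rose there had a median change of 2.70 (quartiles 1.16 and 3.86) from second flush to after second flush, with 24 called up and 0 down, in libraries that share 1 letter, so such changes may occur without that batch, which does not show that none acted at first flush. A biological difference between the stages stays open as well.

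The second pattern is that the same groups were low at second flush and high after it. A swap of the labels of those stages was tested by asking which stage each library resembles, and 2 of 4 libraries correlated more with the stage the other label would give. The after second flush libraries correlated with first flush at 0.931 to 0.933 and the second flush libraries at 0.908 to 0.913, across genes. With after first flush the second flush libraries correlated at 0.967 to 0.968 and the after second flush libraries at 0.956 to 0.962. Set against each other, the pairs thus lean the way a swap would give. All 4 were nearer to after first flush, so the test does not separate the labels, and a swap and the stages cannot be told apart by it. As labelled, hydrophobins went from 1.63% to 0.871% of reads after first flush and from 1.23% to 0.323% after second flush, and fruiting body markers from 0.109% to 0.0407% after second flush, while the markers overlapped after first flush (0.144% and 0.103%, then 0.11% and 0.0429%), camera called neither list there (adjusted p = 0.26 for each), and a swap forbids none of these values.

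The third pattern is the gap between the libraries from after first flush. If replicate 2 were replicate 1 mixed with RNA of first flush compost, 1 mixing share should serve all genes, but over 119 genes the upper quartile of the share was 10.1 times the lower (median 5.2%, quartiles 1.2% and 12.1%), which argues against it. For RNA of after second flush compost, genes higher there needed a share with a quartile ratio of 2.2 (52 genes, median 12.3%, quartiles 7.9% and 17.6%). Genes at least 8 times lower there than in replicate 1 needed a median share of 81.2% (24 genes, quartiles 55.7% and 92.7%), which argues against that mixture as the whole cause. In each of these tests genes were picked by their level in replicate 1, which also enters the share. This may have moved the shares, and the spread that a true mixture would give was not computed. Separate compost samples at different points of the same stage stay open, untested.

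For after flush against flush, 2 of the 35 splits of the 8 libraries into 4 and 4 gave at least as many genes, the real split included, so that test does not exclude chance. It has no term for the flush, so differences between the flushes (4028 genes between first and second flush) add to its spread and lower its power. It therefore says little about the 3189 calls of the full fit, whose spread is that between replicates. In the test of splits the real split gave 1 gene and the highest other 172, for first flush with after second flush against the rest. This points to a structure of the samples. A swap of the second flush and after second flush labels would give that grouping, and so would stages that differ in this way. The count does not tell these apart.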

How the results depend on the processing

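The fits without the libraries of first flush or of after first flush were chosen only after the data were seen. Asking for at least a 2-fold change, the calls were 2345 at pinning, 1796 at first flush, 2070 after first flush, 524 at second flush, 339 after second flush, 1800 for second against first flush, 2551 for the 5 later stages against spawning, 467 for after flush against flush and 2223 for the difference between the after-flush steps, since fewer genes pass a stricter rule. With only the stages compared in the fit, 46 genes were called at second flush and 426 after second flush, with 4 libraries behind the spread. Kept apart from the after first flush libraries, the step to after second flush had 1194 calls (577 apart from the first flush libraries), and the cause was not tested. With an estimated correlation camera called 0 pairs of list and comparison, against 71. It called 73 with a replicate block, though nothing in the labels says that the replicate numbers pair the libraries.

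Leaving out 1 library at a time, where the lone library of a stage is assumed to vary like the other stages, the calls ranged from 3644 to 3853 at pinning, 2893 to 3531 at first flush, 3433 to 4540 after first flush, 809 to 2032 at second flush and 177 to 535 after second flush. The range was 2957 to 3399 for second against first flush, 4461 to 6039 for the 5 later stages, 2362 to 3397 for after flush against flush, 2709 to 3895 for the difference and 6882 to 7660 for any change. At second flush the count was 1226 without second flush replicate 1 and 809 without replicate 2. After second flush it was 330 and 304 without second flush replicates 1 and 2 and 177 without after second flush replicate 1. The cause was not tested.

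Reversals were unlikely from the start, since results were picked as called and the refits reuse the same libraries. Of 332 results for named genes, none reversed. Without 1 library, 216 of the results recomputed for them were no longer called, against 1628 that were. The calls lost in this way were 8 of 45 at pinning, 8 of 44 at first flush, 5 of 47 after first flush, 20 of 38 at second flush and 16 of 31 after second flush. They were 10 of 41 for second against first flush, 5 of 43 for the 5 later stages and 8 of 40 for after flush against flush. DESeq2 size factors ended the call of 1, DESeq2's test of 4, no low-count filter of 5, and limma on log2 RPKM of 15 with a pseudocount of 1 and 17 with 0.1. Which direction had more calls turned with DESeq2 size factors at first flush (2147 up, 2168 down), at second flush (949 up, 1008 down) and for the 5 later stages (2812 up, 2980 down), so no excess of rises over falls is claimed for these. At second flush 34 of 38 named results lost their call with only the stages compared. That fit is the same as the full one for the 5 later stages and for any change, so it was not run there. In the self-test on simulated counts 18% of 1.5-fold changes were recovered. Small changes may thus be missed at this depth and number of libraries, though that share need not hold for the real counts.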

Other observations

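All tests in this part were chosen only after the data were seen. The rises at first flush over pinning and after second flush over second flush, which share no library, fell on some of the same genes: 259 genes rose in both, against 117 if the calls were independent, and 149 fell in both, against 60.2. Only 15 genes rose at first flush and fell after second flush, against 64.1. Across the 8814 genes the log2 changes correlated at 0.39 (Pearson) and 0.35 (Spearman), and genes are not independent replicates. For the cellulose list they correlated at 0.73 and 0.63, for the hemicellulose and pectin list at 0.68 and 0.62, and for the 12 laccases at −0.01 and 0.26. In the lists drawn up later, cellulose genes without the glucan 1,3-beta-glucosidases had 0.87 and 0.89, and the glucan 1,3-beta-glucosidases −0.09 and −0.15.

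Laccase-1 and laccase-2 (gene 139148) are 1 entry apart in the H97 gene table. Laccase-2 stood at 10478 ± 366 RPKM at spawning, 457 ± 93 at pinning and 1610 ± 127 at first flush. The small subunit of laccase-2 (gene 149407) stood at 13140 ± 275 RPKM at spawning. Uncharacterised gene 136557 lies 7 entries from hydrophobin 136569, which lies 11 from hydrophobin 193057.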
